A study of Phalaenopsis amabilis with 10 samples.

How the data were processed

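Small RNA libraries of 10 leaf samples of Phalaenopsis amabilis were analysed from the deposited tables of distinct sequences. Leaves were inoculated with 0.5 µg of virions of each of CymMV and ORSV, or with buffer, and were sorted by a tissue blot at 10 days, per the labels' protocols. RNA was extracted with TriPure reagent, libraries were made with an Illumina small RNA kit and sequenced on a MiSeq in 2 batches, and in batch 2 the 6 libraries were pooled on 2 lanes, per the labels' protocols. Plants were virus-free by multiplex RT-PCR before inoculation, per the labels' protocols.

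The deposited files hold, per the file headers, unique sequences and their abundance count, with no normalization. The trimming tool, the quality filter and any removal of other RNA by the authors are not given in the sources used here. As checked on the values, sequences were 18 to 25 nt long and none had under 6 reads over the 10 files, so rarer sequences had been left out before deposit. Libraries held 1501717 reads (Mi-1), 1546011 (Mn-1), 1965826 (Di), 1571099 (Dn), 2108751 (Mi-2), 2104495 (Mn-2), 2988070 (Dsi-1), 1806623 (Dsn-1), 2420829 (Dsi-2) and 1663129 (Dsn-2), in 212089 to 266225 distinct sequences each. Sequences found in all libraries numbered 45186, and 602 were found in 1. At these depths a share of 0.0027% rests on 42 reads, as for ORSV in Dn. Reads carried no molecular identifiers, so intervals cover counting error only.

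No virus or orchid genome was used here. The longest ORSV contig was grown from the most abundant sequence that encodes 7 residues of the ORSV coat protein, by overlaps of at least 12 nt among sequences of 20 to 24 nt of all libraries. All other contigs were built with a k-mer size of 13 from sequences whose mean level in mock libraries was at most 0.05 of their highest infected level, and those under 50 nt were left out. Markers were a coat protein match (tblastn 2.17.0, e-value 1e-06) and a polymerase motif, written from general knowledge, as was the leaky stop pattern used as a landmark. ORSV gave 3 contigs of 6626 nt in all, with 158 of 158 coat protein residues found, and CymMV gave 14 contigs of 6153 nt, with 205 of 223 residues. Only 7 CymMV contigs carried a marker (3380 nt), so the others were added to the virus whose coat protein contigs their profile over libraries correlated with at 0.9 or more. This departed from the plan, which foresaw marked contigs alone, and marked contigs alone were kept as an alternative. Reads matched a virus where they equalled a stretch of either strand of a contig, and Wilson intervals at 95% were computed for single libraries.

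Families were matched to a list of 31 conserved plant small RNA families written from general knowledge. Sequences of 19 to 23 nt were given to the nearest family within 2 mismatches and 2 nt offset at either end, and 1 sequence with 7 reads that tied between families was left out. Families with a mean of at least 10 reads per library were tested, 22 in all. Members of near-identical families (miR156, miR529 and miR535, or miR159 and miR319) share similar sequences, so their counts rest on this rule. Other RNA classes were matched as exact fragments of at least 17 nt of short conserved rRNA, plastid rRNA and tRNA stretches.

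Samples were grouped by the labels. Families were tested with edgeR 4.0.16's quasi-likelihood test in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05, and with library size fixed to the reads not matching a virus contig. Infected against mock was fitted with batch and leaf position (6 residual degrees of freedom). The other contrasts came from a fit of 6 group means with batch (3 residual degrees of freedom), in which single libraries are assumed to vary like the other groups. SE was the log2 fold change divided by the square root of the test statistic. Family lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1), for lists with at least 3 tested families. Fry's main p asks whether a list moves on balance in 1 direction and its mixed p whether members change in either direction. Distinct sequences not matching a virus contig and with at least 10 reads in total were filtered with filterByExpr defaults, scaled with TMM and tested in the same 2 designs, 17964 sequences for infected against mock and 31257 for the group contrasts. Shares were compared with exact two-sided permutation tests over 210 permutations. Tables were handled with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

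Named families were those that passed, at most 12 per comparison by smallest p, plus the lists of RNA silencing factors and copper-responsive families. Named sequences were the 5 of smallest p in either direction, at most 3 per family. Virus-like sequences were counted but skipped in naming, as were unnamed sequences whose mean mock level was at most 5% of their highest infected level, which departed from that rule so that no sequence of another organism is printed. The families miR171, miR396 and miR5179 fall outside the rule and were named after their values were seen, as was miR529 in the test between leaf positions.

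The family test was tested on simulated data, with 50 sets of counts drawn for the 22 families. In infected against mock, 65% of 2-fold and 96% of 4-fold changes were called, and 1.22% of unchanged families. In Di against Mi 9% and 48% were called and 1% of unchanged families, and in Dsi against Mi 7% and 56% and 1.33%. For the 17964 sequences of infected against mock, 15% of 2-fold and 87% of 4-fold changes were called and 0.0225% of unchanged sequences.

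Alternatives planned in advance were DESeq2 1.42.0 with its size factors, TMM over the families, all deposited reads as library size, library size without TMM for sequences, an estimated correlation for family lists, no filter on low counts, a mean of at least 50 reads, exact matches to a listed sequence, no batch term, batch 2 alone, a replicate block, removal of sequences within 1 mismatch of a virus contig, distinct sequences in place of reads, reads of 20 to 24 nt, and each library left out in turn. Alternatives chosen after seeing the data were batch 1 alone, batch 2 alone for sequences, no Dsn libraries, no miR166 in the library size, reads within 1 mismatch of a virus left out of the library size, removal of sequences sharing 15 nt of their start with a virus contig, and marked contigs alone. No overlap of calls was computed between comparisons that share mock libraries. Positions on CymMV contigs were left out, since their order was not established.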

Results

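Small RNAs were sequenced from leaves of the moth orchid Phalaenopsis amabilis after inoculation with a mixture of Cymbidium mosaic virus (CymMV, a potexvirus) and Odontoglossum ringspot virus (ORSV, a tobamovirus), or with buffer alone. The 10 libraries formed 6 groups. Mi (n = 2) was the rubbed area of mock leaves and Mn (n = 2) the untreated area next to it. Di (n = 1) was the inoculated area of leaves in which CymMV had spread, and Dn (n = 1) the adjacent area reached by CymMV. Dsi (n = 2) was the inoculated area of leaves in which the tissue blot at 10 days showed no spread, and Dsn (n = 2) the adjacent area of those leaves. The labels rank Dsn, Dsi and Di as early, intermediate and late stages of infection. Mi-1, Mn-1, Di and Dn were sequenced as batch 1, and the other 6 libraries as batch 2.

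The files held 19676550 reads of 18 to 25 nt in 392837 distinct sequences, with 1501717 to 2988070 reads per library. Di and Dn had no replicate, so their comparisons borrowed the spread of the other groups. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these samples. Within the replicated groups, counts of the abundant sequences differed by more than sampling noise, with a chi-square per degree of freedom of 15.4 in Dsn, 70.5 in Mn, 80.0 in Mi and 104 in Dsi.

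Virus-derived reads made up a large part of every library from inoculated, infected tissue. In Di, 18.8% of reads matched CymMV (95% Wilson interval 18.8% to 18.9%) and 24.5% matched ORSV (24.5% to 24.6%). In Dsi, ORSV took 49.9% and 26.4% of reads in the 2 libraries, and CymMV 9.26% and 9.89%. Dn held CymMV at 3.97% (3.94% to 4.00%) but ORSV at 0.00267% (0.00198% to 0.00361%), which lay within the range of the batch 1 mocks, 0.00193% in Mi-1 and 0.00310% in Mn-1. The Dsn libraries held 0.0745% and 0.229% of virus reads in total, beside 0.0345% in Mi-2 and 0.109% in Mn-2. Mn-1, a mock library, held CymMV at 0.581% (0.569% to 0.593%), a level reached by no other mock and by neither Dsn library. These intervals cover counting error only.

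The virus share averaged 23.8% ± 25.7 (SD, n = 6) in infected and 0.183% ± 0.271 (SD, n = 4) in mock libraries, a difference of 23.7 percentage points with 4 of 6 infected libraries above every mock. All contigs but the longest of ORSV were built from sequences scarce in mock libraries. The difference did not pass an exact two-sided permutation test (p = 0.0667, adjusted p = 0.267 over 4 shares; the smallest p that 6 against 4 libraries allow is 0.00952). The difference was 23.4 points within batch 1 and 23.9 within batch 2. Without the Dsn libraries it was 35.5 points (exact p = 0.0286), and without the mock library Mn-1 it was 23.8 points (exact p = 0.0476). Without Dsn-1 or Dsn-2 the exact p was 0.0317 or 0.0476, and with marker-bearing contigs alone it was 0.0476.

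**Figure D1:**
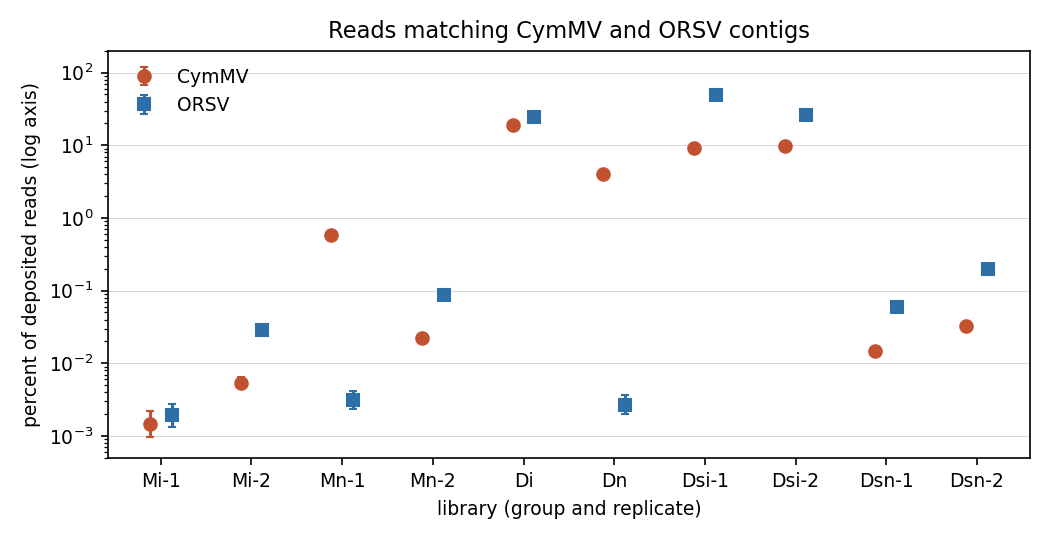
Percent of deposited reads (log axis) that matched CymMV contigs (circles) or ORSV contigs (squares) in each of the 10 libraries, with 95% Wilson intervals as bars. ORSV lay at 24.5% in Di and at 26.4% and 49.9% in Dsi but at 0.00267% in Dn, where CymMV lay at 3.97%.

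Reads of both viruses were mostly 21 nt long and came from both strands. ORSV reads of Di and Dsi were 71.3% to 75.4% 21 nt long and 15.1% to 16.4% 22 nt long, and 56.1% to 59.4% of them were of the sense strand. CymMV reads of Di, Dn and Dsi were 57.4% to 58.7% sense. The 22 nt class of CymMV was larger in Dn, at 25.3% of reads with a 22 nt to 21 nt ratio of 0.425, than in Di (ratio 0.264) or in the Dsi libraries (17.8% and 16.6%, ratios 0.259 and 0.239). Mn-1 had a ratio of 0.380. Counted over distinct sequences, the ratio was 0.553 in Dn, 0.501 in Di and 0.491 and 0.486 in Dsi, so the groups lay closer together. No test was made of these shares. The first base of CymMV reads was C in 34.5% of Di, 33.4% of Dn and 32.1% of either Dsi library, and U in 24.2% to 25.4%. ORSV reads began with U in 31.4% to 32.3%, with A in 29.2% to 30.5% and with C in 28.2% to 31.7%.

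Along the longest ORSV contig of 6391 nt, the coat protein region (5723 to 6196) held more reads than its length would give. It took 12.9% of the reads on that contig in Di and 14.1% and 13.4% in Dsi, for 7.42% of the contig's length. The part before the leaky stop at 3401, which ends the shorter replicase protein, took 52.1% of them in Di and 51.4% and 50.1% in Dsi, for 53.2% of that length. CymMV contigs that matched the coat protein held 2.64% of CymMV reads in Di, 2.79% in Dn and 2.62% and 2.11% in Dsi, for 10.3% of the CymMV length assembled. Those contigs were only 54 to 161 nt long, and a read counted only where it lay wholly inside a contig. Reads across contig ends were lost, which lowers the share of short contigs more than that of long ones. These shares therefore do not show that the CymMV coat protein region gave fewer reads. CymMV was assembled in 14 pieces, so its reads are given per group of contigs and not along the genome.

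**Figure D2:**
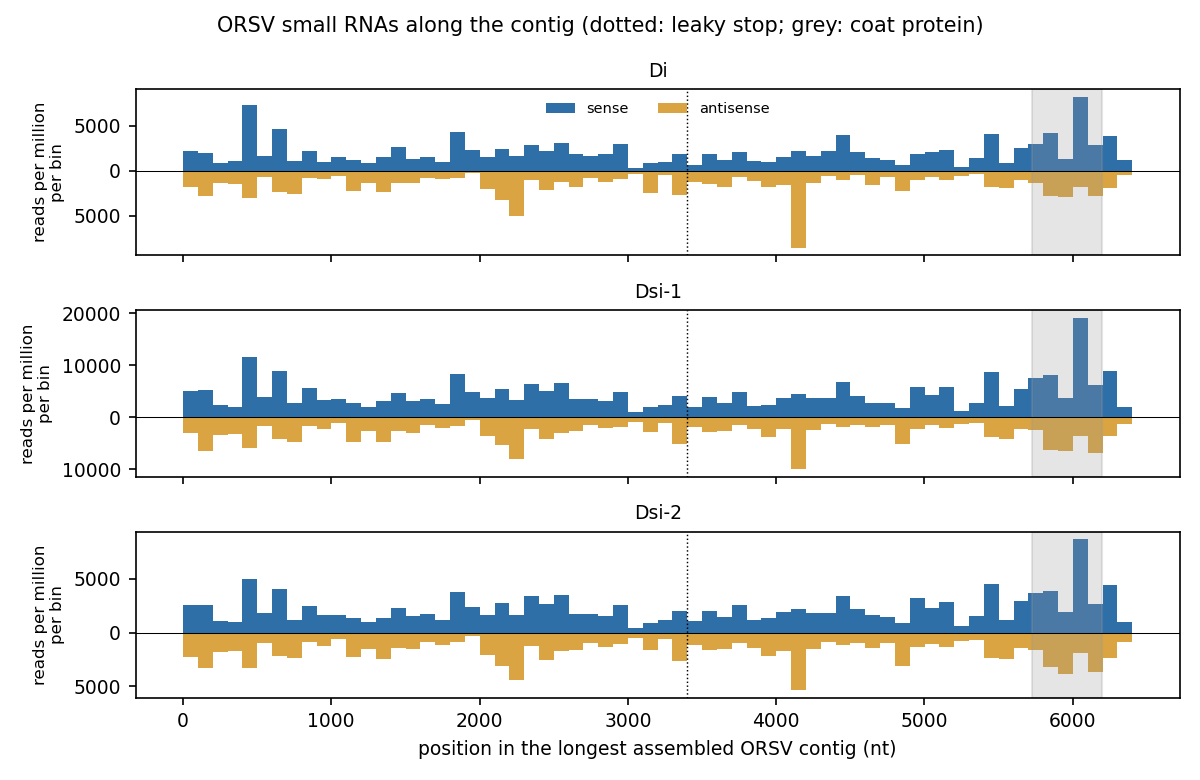
ORSV RPM of deposited reads in bins along the longest assembled contig (nt), sense above and antisense below the line, in Di and the 2 Dsi libraries. The grey band is the coat protein region from 5723 to 6196, which held 12.9% to 14.1% of the reads on that contig, and the dotted line is the leaky stop at 3401.

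Among all reads, the 21 nt class dominated and the 24 nt class came next in the mocks. The 21 nt share averaged 37.9% ± 12.7 (SD, n = 6) in infected and 30.2% ± 1.99 (SD, n = 4) in mock libraries, a difference of 7.71 points that was within the spread of the infected libraries (exact permutation p = 0.314, adjusted 0.333). Its sign depended on virus reads: among reads not matching a virus contig, the share was 27.8% in infected and 30.2% in mock libraries, a difference of -2.33 points (exact p = 0.181). The 22 nt share was 15.5% ± 1.31 against 14.4% ± 1.11 (exact p = 0.229, adjusted 0.333). The 24 nt share was 17.4% ± 6.19 against 22.2% ± 0.381, a difference of -4.86 points (exact p = 0.333, adjusted 0.333), which was -0.408 points among reads not matching a virus contig (21.9% against 22.3%, exact p = 0.667). Over distinct sequences the 24 nt difference was -5.71 points with 5 of 6 infected libraries below every mock (exact p = 0.0381), but there virus sequences were counted too, and they made up 15.1% to 17.1% of distinct sequences in Di and Dsi. Within batch 1 and batch 2 the differences were 8.67 and 7.49 points for 21 nt, 0.825 and 0.946 for 22 nt, and -4.08 and -5.24 for 24 nt.

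**Figure D3:**
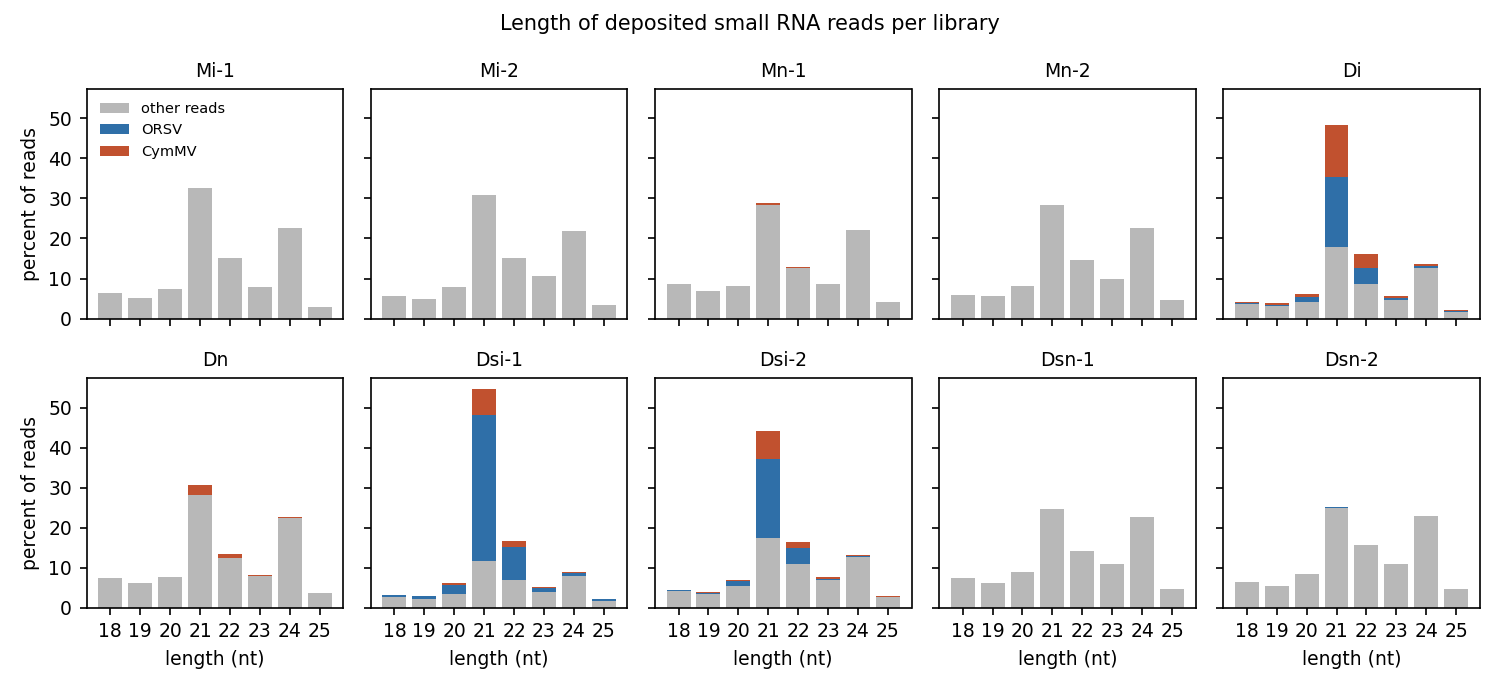
Percent of deposited reads at each length from 18 to 25 nt in the 10 libraries, with reads that matched ORSV, CymMV or neither stacked. In Di and Dsi virus reads add to the 21 nt bar, which reached 54.6% in Dsi-1 against 28.4% to 32.7% in the mocks.

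Fragments of other RNA classes were scarce. Fragments of tRNA made up 0.504% to 0.756% of non-virus reads in the 4 Dsi and Dsn libraries, and 0.295% to 0.378% in the other 6, Di and Dn included. Over all libraries their share was 0.529% ± 0.166 (SD, n = 6) in infected against 0.340% ± 0.0368 (SD, n = 4) in mock (exact permutation p = 0.0571). Plastid rRNA fragments were at 0.263% against 0.185% (exact p = 0.0857) and cytosolic rRNA fragments at 0.228% against 0.230% (exact p = 0.895).

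Conserved microRNA families took 10.5% to 16.9% of non-virus reads. Of 31 listed families, 25 had reads and 22 were tested. The family miR166, which targets HD-ZIP III transcription factors, was the largest, with 108963 to 118808 RPM (non-virus reads scaled to a common library size) in the mocks. The families miR397, miR403, miR444, miR482, miR827 and miR858 had no read. Fold changes were scaled to non-virus reads, and other scalings moved the median over the 22 families: in Dsi against Mi it was 0.01, with 0.19 by TMM over the families and -0.90 by all deposited reads, and in Di against Mi it was -0.25, 0.11 and -1.07. In infected against mock all deposited reads moved it from 0.14 to -0.33 and in Dsi against Dsn from -0.11 to -1.06. TMM moved it from 0.26 to 0.10 in Dsn against Mn, from 0.22 to -0.01 in Dn against Mn, from 0.37 to -0.10 in Mi against Mn and from -0.21 to -0.05 in Di against Dsi.

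Over all infected against all mock libraries (6 against 4), 3 families changed, 1 up and 2 down. The miR319 family, which targets TCP transcription factors, rose by 1.57 ± 0.40 on the log2 scale (SE; adjusted p = 0.0383). Both miR166 and the tasiARF small RNAs, which come from TAS3 transcripts and target auxin response factors, fell, miR166 by 0.40 ± 0.11 (adjusted p = 0.0383) and tasiARF by 1.28 ± 0.38 (adjusted p = 0.0383). The tasiARF family held 700 reads, of which 24 matched a listed sequence without mismatch. The AGO1-targeting family miR168 stood at 0.77 ± 0.31 (adjusted p = 0.155), the DCL1-targeting family miR162 at 0.19 ± 0.19, and the copper-responsive families miR398 and miR528 at 0.66 ± 0.52 and 0.20 ± 0.38, none of which passed. With all deposited reads as library size, miR162 and miR528 turned to -0.29 and -0.27.

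These came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where 6 families had an unadjusted p under 0.05. The 2 batches differed: within batch 2, miR319 stood at 2.41, miR166 at -0.65 and tasiARF at -1.58, with 4 families called, while within batch 1 they stood at 0.56, -0.05 and -0.56, with none called and 1 at an unadjusted p under 0.05. Without batch as a term 0 families passed (1 unadjusted) and miR319 stood at 0.90, and DESeq2 called 7, of which 1 was higher. The miR166 call ended with TMM (adjusted p = 0.124) and the miR319 call with all deposited reads (0.108). The count was 0 without Dsi-2, Dsn-1, Dsn-2, Mi-2 or Mn-2 in turn and without both Dsn libraries, 1 (miR319) without Dsi-1, and 7 without Mn-1, the mock library with CymMV reads. The tasiARF call also ended without Mi-1 (adjusted p = 0.186) or Di (0.129).

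In the inoculated area without spread against mock (Dsi against Mi, 2 against 2 libraries), 5 families changed. The miR168 family rose by 1.66 ± 0.40 (adjusted p = 0.0129), from 1714 and 3226 RPM in Mi to 7120 and 3479 in Dsi. The miR319 family rose by 2.33 ± 0.46 (adjusted p = 0.00427). Families that fell were miR166, by 0.71 ± 0.10 (adjusted p = 5.8e-04), tasiARF, by 2.36 ± 0.62 (adjusted p = 0.0176), and miR529, which targets SPL transcription factors, by 1.86 ± 0.56 (adjusted p = 0.0331). In the list of RNA silencing factors 2 of 3 tested families changed, miR168 and tasiARF, of which tasiARF targets auxin response factors, and miR162 stood at 0.05 ± 0.29. Neither copper-responsive family tested passed, with miR398 at -0.12 ± 0.80 and miR528 at 0.11 ± 0.56. Signs of these 3 families depended on the library size: miR162 and miR528 were at -0.86 and -0.87 with all deposited reads, and miR398 at 0.03 with TMM.

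The miR168 change rested on sequences other than the listed ones, since exact matches alone gave 0.31 (adjusted p = 0.615). Its value was 0.61 (adjusted p = 0.175) with all deposited reads as library size. The call for tasiARF ended without Dsi-2 (adjusted p = 0.0930). That for miR529 ended within batch 2 alone (adjusted p = 0.0809), with DESeq2 (0.0508), and without Mi-1, Mn-1, Mn-2, Dsi-1 or Dsi-2 in turn (adjusted p from 0.0747 to 0.132). For miR166, TMM over the families gave -0.54 (adjusted p = 0.111) and DESeq2 -0.54 (adjusted p = 0.314). Without batch as a term miR166 alone passed, and miR319 stood at 0.67 and miR168 at 1.10. The miR168 value was 1.05 without Dsi-1, and without Mi-2 tasiARF and miR529 stood at -3.87 and -2.83. The count was 3 without Dsi-2, and 8 families had an unadjusted p under 0.05.

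In the adjacent area of the same leaves (Dsn against Mn, 2 against 2), 3 families changed. The miR319 family rose by 2.48 ± 0.48 (adjusted p = 0.00393), from 1162 and 155 RPM in Mn to 1046 and 929 in Dsn, of which 155 was the Mn library of the same batch. The miR535 family, related to miR156 and miR529, rose by 1.77 ± 0.50 (adjusted p = 0.0367). The miR166 family fell by 0.58 ± 0.10 (adjusted p = 0.00342). No family of the RNA silencing or copper-responsive lists passed: miR168 stood at 0.31 ± 0.39, miR162 at 0.53 ± 0.29, tasiARF at -0.95 ± 0.54, miR398 at -0.66 ± 0.78 and miR528 at -0.85 ± 0.65. Mn-2 was the only Mn library of batch 2, and without it 0 families passed (4 at an unadjusted p under 0.05). Without batch as a term miR166 alone passed, with miR319 at 0.59 and miR535 at 0.84, and with TMM or all deposited reads miR319 alone did. The miR535 call also ended without Dsi-2, Dsn-1 or Dsn-2 (adjusted p from 0.0514 to 0.175), with exact matches (adjusted p = 0.194) and with TMM (adjusted p = 0.0704). The miR166 call ended with TMM (adjusted p = 0.0704), DESeq2 (0.0696) and all deposited reads (0.395).

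Across Dsi and Dsn, miR166 was lower at either position, at 64192 to 74231 RPM against 113102 and 108963 in the batch 2 mocks. Those mocks and the Dsi and Dsn libraries also differed in the reads of miR166 that carry a base substitution, with a chi-square per degree of freedom of 26.8 against 13 for the highest of the other 14 ways to part the 6 libraries into 2 and 4. All 6 nevertheless shared a substitution at position 10 of miR166, counted from its 5′ end, at 1.63% to 2.07% of the unsubstituted reads, against at most 0.0383% in batch 1.

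In the inoculated area of leaves with CymMV spread (Di against Mi, 1 against 2), no family passed edgeR's quasi-likelihood test, with 2 at an unadjusted p under 0.05 and 0 by DESeq2. Those were miR398, which targets copper/zinc superoxide dismutases, at 2.33 ± 0.92 (adjusted p = 0.335), and miR171 at -1.87 ± 0.75 (adjusted p = 0.335). With exact matches miR398 alone passed, at 2.31 (adjusted p = 0.0276). Its value was 3.39 without Mi-2, Mn-1 or Mn-2, where each fit set Di against Mi-1 alone. It was 2.29 without Dsn-1 but 0.74 without Mi-1, and 226 reads lay behind it in all. The other families followed by name stood at 1.29 ± 0.75 for miR528, 0.74 ± 0.45 for miR168, -0.20 ± 0.34 for miR162 and -1.58 ± 0.79 for tasiARF. With all deposited reads miR168 turned to -0.08, and with TMM miR162 turned to 0.17. Simulated 4-fold changes were called in 48% of cases in this comparison.

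In the adjacent area reached by CymMV (Dn against Mn, 1 against 2), no family passed the same test, 0 had an unadjusted p under 0.05, and DESeq2 called 0. The largest value was miR398 at 1.67 ± 0.76 (adjusted p = 0.943). The family miR528 stood at 0.74 ± 0.66, miR162 at 0.32 ± 0.34, miR168 at 0.28 ± 0.45 and tasiARF at 0.11 ± 0.75. The last 3 changed sign with DESeq2's size factors, to -0.05, -0.10 and -0.19. The mock library Mn-1 resembled Dn in CymMV reads and in high levels of both copper-responsive families. It held miR398 at 21.5 RPM against 2.66 in Mi-1, and miR528 at 433 against 93.9, where Dn held 50.4 and 530. Over host sequences it correlated at 0.926 with Dn and at 0.843 with Mi-1. Without Mn-1 miR398 stood at 3.88 in Dn against Mn. That fit set Dn against Mn-2 of the other batch, at 9.51 RPM. It took the batch from Mi-1 and Mi-2 alone, at 2.66 and 7.59 RPM, so 3.88 rests on the low library Mi-1 as well.

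**Figure D4:**
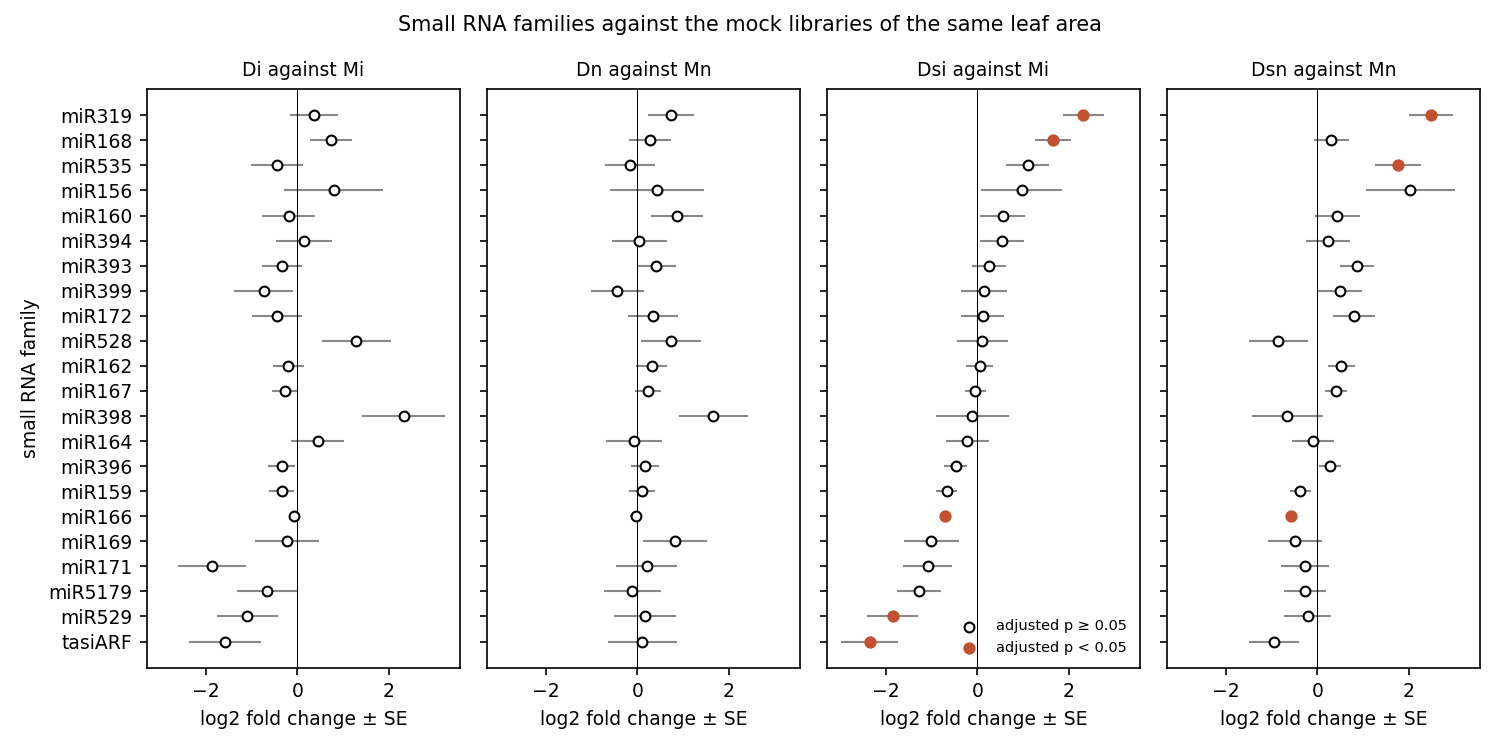
Log2 fold change of 22 small RNA families against mock libraries of the same leaf area, with SE as bars, in Di, Dn, Dsi and Dsn. Filled points have an adjusted p under 0.05: 5 families in Dsi, 3 in Dsn and none in Di or Dn.

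Late infection with spread was set against infection without it (Di against Dsi, 1 against 2). The miR166 family was higher in Di by 0.65 ± 0.14 (adjusted p = 0.0212), and 4 families had an unadjusted p under 0.05. The batch is known here only through the mocks. The miR166 call ended with TMM (adjusted p = 0.279), DESeq2 (0.707), all deposited reads (0.631) and without both Dsn libraries (0.0757), and also without Mi-1, Mi-2, Mn-1, Mn-2, Dsn-1 or Dsn-2 in turn (0.0693 to 0.159). The count was 3 without Dsi-2 and with exact matches. The families miR168, at -0.92 ± 0.55, miR398, at 2.45 ± 1.08, and tasiARF, at 0.78 ± 0.95, did not pass.

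Inoculated and adjacent areas of leaves without spread differed in 1 family (Dsi against Dsn, 2 against 2). The miR168 family was higher in the inoculated area by 1.72 ± 0.35 (adjusted p = 0.0125), and it passed whichever library was left out, at 1.11 without Dsi-1 and 2.15 without Dsi-2. It did not pass with TMM (1.52, adjusted p = 0.0660), with exact matches (0.39, adjusted p = 0.521), without batch as a term (1.72, adjusted p = 0.204) or with all deposited reads (0.67, adjusted p = 0.105), where 7 families were lower. The count was 2 without Dsi-2 and without Dsn-1. The same areas of mock leaves (Mi against Mn, 2 against 2) differed in 0 families by edgeR's quasi-likelihood test and in 0 by DESeq2, with 2 at an unadjusted p under 0.05. In mock leaves miR168 stood at 0.37 ± 0.35, and that value was -0.10 with TMM. That count was 1 without Dsi-1 or Dsi-2 and 3 without Mi-2 or Mn-2.

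The difference between these contrasts was tested directly for all 22 families. The effect of infection without spread was larger at the inoculated position for miR168 by 1.35 ± 0.49, which failed adjustment (unadjusted p = 0.0196, adjusted p = 0.293). The miR529 and miR396 families stood at -1.64 ± 0.70 and -0.75 ± 0.32 in that test, and 0 families passed (3 unadjusted, 2 passing without Dsi-2). For leaves with spread 0 passed in the same test (1 unadjusted).

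**Figure D5:**
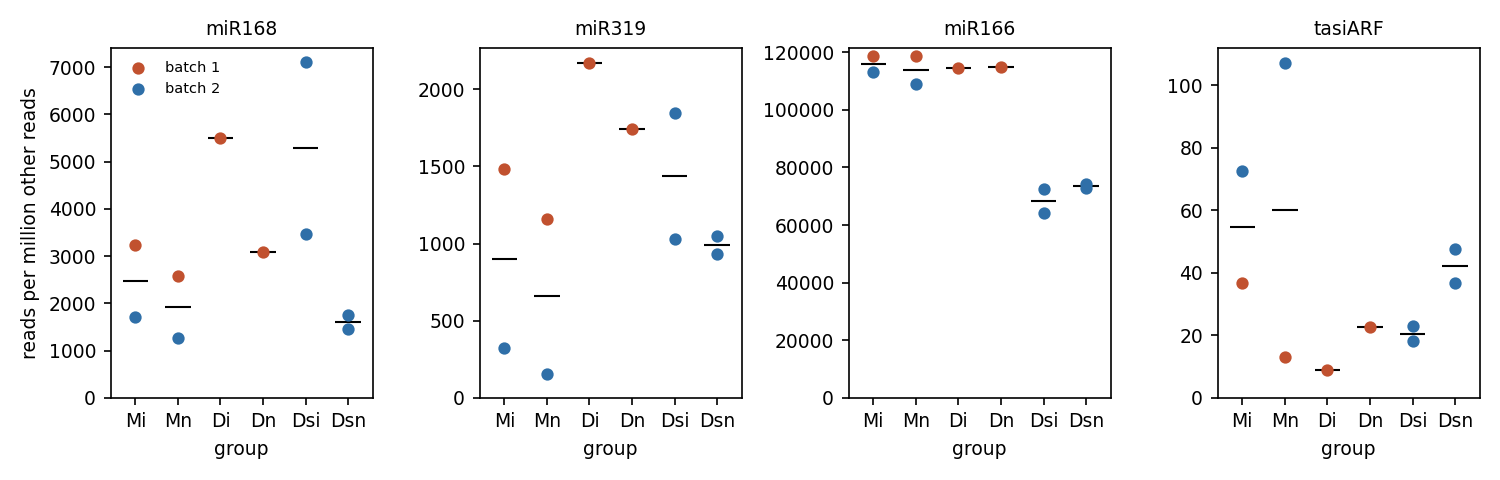
RPM of non-virus reads for miR168, miR319, miR166 and tasiARF in each library by group, with points coloured by batch and group means as lines. In miR168 the Dsi libraries lie at 7120 and 3479 against 1456 and 1760 in Dsn, and in miR166 all 4 Dsi and Dsn libraries lie below the 6 others.

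Lists of families were fixed before the data were examined. Of the 11 developmental transcription factor families, 1 rose (miR319) and 1 fell (miR166) in infected against mock, 2 when adjusted over the list alone, and fry's test for change in either direction passed (adjusted p = 0.0315) while its test for a shared direction did not (adjusted p = 0.891). In Dsi against Mi 1 of them rose and 2 fell, and in Dsn against Mn 2 rose and 1 fell, or 4 and 3 adjusted over the list alone. Of the 3 families of the RNA silencing list, 1 passed in infected against mock (tasiARF, lower), or 2 adjusted over the list alone, where miR168 (higher) joined. Of the 4 auxin pathway families 1 fell, tasiARF again, and 1 did adjusted over the list alone. Camera called 0 of these 3 lists at its preset correlation of 0.01, 0 at an unadjusted p under 0.05 and 0 with an estimated correlation (adjusted p = 0.938 for each). The signs of summaries differed: the silencing list had a median of 0.19, a mean of -0.11 and an upward camera direction, the auxin list 0.21, -0.10 and upward, and the developmental list -0.09, 0.08 and downward. The copper-responsive list kept 2 tested families (miR398, miR528) and the nutrient list 1 (miR399), with none called in any comparison. The monocot MADS list kept 1 tested family, miR5179, so adjustment over that list alone leaves its p unchanged. By edgeR's quasi-likelihood test miR5179 stood at -0.63 ± 0.28 in infected against mock (unadjusted p = 0.0449). In Dsi against Mi it stood at -1.27 ± 0.49 (unadjusted p = 0.0247). Adjusted over all tested families it passed in neither (adjusted p = 0.160 and 0.0775). The immune receptor list kept none.

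At the level of distinct sequences, the balance of higher and lower calls depended on virus-like sequences and on batch. In infected against mock without batch as a term 85 rose and 1 fell, and in Dsi against Mi 708 rose and 9 fell. Within batch 1 alone, infected against mock gave 42 up and 0 down. These counts include virus-like sequences. In infected against mock, 981 of 17964 tested sequences passed, 662 up and 319 down. Of the 662, 348 lay within 1 mismatch of a virus contig or shared its start and 49 others were scarce in mocks, which left 265 up against 319 down. The step for sequences scarce in mocks had no counterpart for fallen sequences. It lowers the risen count alone, here and in Dsi against Mi. With sequences within 1 mismatch removed the count was 638, 325 up and 313 down. In Dsi against Mi 1645 of 31257 passed, 1184 up and 461 down, of which 627 were virus-like and 89 others scarce in mocks, which left 468 up against 461 down. With removal 907 did, 524 up and 383 down. In Dsn against Mn 151 passed, 82 up and 69 down, none of the 82 virus-like and 3 scarce in mocks. Sequences of 24 nt were 6.50% of the risen and 2.51% of the fallen in infected against mock, against 23.3% of those tested. Members of miR166 were among the fallen in each comparison (16, 22 and 17) and members of miR319 among the risen (7, 6 and 5). The named miR166 members among them were substituted copies of a far more abundant sequence, as given below.

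The sequence with the largest named rise that belonged to a family was a miR168 variant, TCGCTTGGTGCAGGTCGGGAC, which rose by 4.80 ± 0.43 in Dsi against Mi (adjusted p = 1.0e-09). It averaged 2553 RPM in Dsi and stood at 2162 in Di, against 173 in Mi, 325 in Dn and 99.2 in Dsn. CCTATGCCTACCTCTTCCACT rose by 5.32 ± 0.55 (adjusted p = 2.5e-08), with 184 in Dsi and 281 in Di against 8.46 in Mi. CCTGCCTTGCATCAACTGAAT rose by 3.91 ± 0.42 (adjusted p = 4.7e-08), with 511 in Dsi, 281 in Di and 61.7 in Mi. Overlapping sequences without a family rose at either position, GCGGACTGCTTGAGCTGCGCC by 3.81 ± 0.38 in Dsi against Mi and CGGCGGACTGCTTGAGCTGCG by 2.44 ± 0.37 in Dsn against Mn (adjusted p = 4.5e-04). The former stood at 493 in Di and 213 in Dn, against 134 in Mi and 204 in Mn. The latter stood at 158 in Di and 66.9 in Dn, against 162 in Mi and 68.9 in Mn, so it was not higher in leaves with spread. In Dsn against Mn the miR319 sequence TTGGACTGAAGGGAGCTCCCT rose by 2.40 ± 0.35 (adjusted p = 2.8e-04) and the miR535 sequence TTGACAAAGAGAGAGAGCACG by 2.75 ± 0.42 (adjusted p = 4.5e-04). The Mn libraries differed widely in both. The miR319 sequence averaged 406 RPM in Dsn and 282 ± 298 (SD) in Mn, and the miR535 sequence 112 and 56.8 ± 62.2.

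Among sequences that fell, AACTTATTAGATACCGTGGACC dropped by 3.08 ± 0.40 in infected against mock and AACTTATTAGATACCGTGGAAC, which has 16.3 times its reads, dropped by 3.10 ± 0.43 in Dsi against Mi. ACGAGCTAGGACACGAGTAGA dropped by 3.84 ± 0.49 in Dsi against Mi. The named miR166 members that fell, TCGCACCAGGCTTCATTCCCC, TCGTACCAGGCTTCATTCCCC and TAGGACCAGGCTTCATTCCCC, each lay 1 substitution from a miR166 sequence with 1959 to 4789 times their reads. Sequences 1 substitution from one at least 10 times as abundant were a larger share of calls in either direction than of tested sequences, which was not tested. Virus-like calls were not left out, 348 of the 662 risen in infected against mock and 627 of the 1184 in Dsi against Mi. Virus reads could also be the more abundant neighbour, so the risen shares may partly reflect virus sequences. They made up 12.4% of risen and 6.58% of fallen sequences in infected against mock (4.51% of tested), 19.2% and 9.76% in Dsi against Mi, and 13.4% and 26.1% in Dsn against Mn (2189 of 31257 tested in both).

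Counts of sequences came from edgeR's quasi-likelihood test, in which 391, 317 and 130 passed by DESeq2, and 86, 717 and 0 (2491 unadjusted) without batch as a term. In infected against mock 1603 passed within batch 2 and 42 within batch 1, 444 without Mi-2, 1572 without Dn, 1669 without Dsn-2 and 2305 without Mn-1. In Dsi against Mi 178 passed without Mi-2, 809 without Dsi-1 and 1029 without Mn-1. In Dsn against Mn 0 passed without Mn-2 (1213 unadjusted), 77 without Dn, 260 without Di, 253 without Dsi-1 and 237 without Dsi-2.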

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

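The tests of carry-over from Di, of a low virus level in Dsn, of how substituted reads part the batch 2 libraries (by chi-square and by position), of read errors shared by them, of miR166 across the batches and of lost miR166 reads were chosen only after the result was seen.

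The miR396 family stood at 16982 RPM in Mi-1, far from the other 3 mock libraries at 8178 to 9527. The miR529 family stood at 73.7 RPM in Dsn-1, far from the other 5 infected libraries at 31.4 to 44.6. These were 2 of 58 groups looked at for a library far from the rest, and chance alone sets apart about 1 in 20 groups. The effect on miR166 differed between inoculated areas with and without spread, by 0.65 ± 0.14 on the log2 scale (Di against Mi less Dsi against Mi, adjusted p = 0.0212 by edgeR's quasi-likelihood test). That call ended with TMM (adjusted p = 0.279), DESeq2 (0.707), all deposited reads (0.631), without both Dsn libraries (0.0757), and without Mi-1, Mi-2, Mn-1, Mn-2, Dsn-1 or Dsn-2 in turn (0.0693 to 0.159), and Di is a single library of the other batch.

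The mock library Mn-1 held CymMV reads at 0.581% of its total, although plants were virus-free by RT-PCR before inoculation, per the labels. Reads carried over from Di would have brought ORSV as well, but Mn-1 held 0.00535 ORSV reads per CymMV read, while Di held more ORSV than CymMV. Counts of CymMV sequences in Mn-1 against Dn gave a chi-square per degree of freedom of 1.72, between the bounds of 1.5 and 2 set for and against carry-over from Dn after library preparation, where Di thinned to the same depth gave 2.36 against Dn and Dsi-1 thinned alike gave 1.49 against Dsi-2. Since the value lies between the bounds, carry-over from Dn, Dn tissue mixed into Mn-1 and virus in the mock leaf itself cannot be told apart, and of these carry-over alone was tested.

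The Dsn libraries held few virus reads, at 0.0745% and 0.229%. Carry-over from Dsi after library preparation stays open: counts of virus sequences pooled over Dsn followed those of Dsi with a chi-square per degree of freedom of 1.19, within the bound of 1.5, but Dsn-2 alone gave 1.60 on 49 sequences, above it, and Dsn-1 gave 0.814 on only 3. For scale, Dsi-1 thinned to the pooled depth gave 1.83 against Dsi-2, pooled Dsn gave 4.94 against Di, and the pooled batch 2 mocks gave 1.15 against Dsi. A low virus level in the adjacent area cannot be told apart from it, because 1 of the 2 Dsn libraries, Dsn-2, lay above both batch 2 mocks in virus share and the other did not.

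The mock libraries of batch 2 parted from Dsi and Dsn in miR166 and miR319 at either leaf position, and tRNA fragments were also at 0.504% to 0.756% in Dsi and Dsn against 0.295% to 0.378% in the other 6 libraries. Per the labels' protocols the 6 libraries of batch 2 were pooled on 2 lanes, which goes against separate sequencing runs of the 2 sets. The values alone leave such runs open, because they point both ways. At 6 read positions of 5 abundant sequences both sets shared errors that batch 1 lacked, the set with fewer at no less than 0.753 of the rate of the other. At 32 of 102 positions, however, both mocks lay wholly above or below the Ds libraries, against at most 19 for the other splits into 2 and 4. By chi-square the split into mock and Ds ranked first of 15 in 3 of 4 sequences other than miR166. The planned test, on distances between profiles, found the split in 0 of the 4, which its bound counted against separate runs, but distances within the sets of up to 1.68 gave it little power. The mean change of miR166 in Di and Dn was 0.0784 times that in Dsi and Dsn, under the bound set for a separate run. Still, these values cannot tell apart a run, which the pooling on shared lanes goes against, a separate library preparation and infection stage. All would coincide with the mock and Ds sets of batch 2. Substituted miR166 reads differed by -0.293 percentage points between the sets, within the bound set against their loss from the family. That test cannot decide the question, because reads with 1 substitution still count in a family that allows 2 mismatches. Reads with more mismatches were not counted.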

How the results depend on the processing

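The tests with batch 1 alone, batch 2 alone for host sequences, no Dsn libraries, changed virus or miR166 reads in the library size, marked contigs alone and removal by a shared start were chosen only after the result was seen. Groups of 1 or 2 libraries and low counts (226 reads of miR398, 700 of tasiARF) limit what follows, and unless named the cause was not tested. Family counts (edgeR) in infected against mock (3) were 7 with DESeq2 and 0 with batch 1 only (1 unadjusted), without batch (1 unadjusted) or without the Dsn libraries (6 unadjusted). They ranged from 0 (without Mi-2, Mn-2, Dsi-2, Dsn-1 or Dsn-2) to 7 (without Mn-1) over left-out libraries, with 1 without Dsi-1. Dsi against Mi (5) gave 8 with all deposited reads and 1 without batch, and 3 (without Dsi-2) to 5 over left-out libraries. Dsn against Mn (3) gave 1 with TMM, all deposited reads or without batch, and 0 (without Mn-2, 4 unadjusted) to 4. Di against Dsi (1) gave 0 with DESeq2 (2 unadjusted), TMM (2), all deposited reads (1) or without the Dsn libraries (3) and 3 with exact matches, and 0 (without Mi-1, Mi-2, Dsn-1 or Dsn-2) to 3 (without Dsi-2). Its 1 call was miR398 in place of miR166 without Mn-1 or Mn-2. Dsi against Dsn (1) gave 0 with TMM (4 unadjusted), exact matches (1) or without batch (1) and 7 with all deposited reads, and 1 to 2 (without Dsi-2 or Dsn-1). Di against Mi (0, 2 unadjusted) gave 1 with exact matches and 0 to 1 (without Mi-2, Mn-1, Mn-2 or Dsn-1), Mi against Mn (0, 2 unadjusted) 0 to 3 (without Mi-2 or Mn-2, and 1 without Dsi-1 or Dsi-2), and Dn against Mn (0, 0 unadjusted) 0 throughout. Host sequence counts in infected against mock (981) were 391 with DESeq2, 4267 with no filter (more sequences tested), 105 with a mean of at least 50 reads (fewer tested), 86 without batch, 638 with virus sequences removed with up to 1 mismatch, 614 with those sharing 15 nt of their start removed as well, 1603 with batch 2 only and 42 with batch 1 only. They ranged from 444 (without Mi-2) to 2305 (without Mn-1), with 1572 without Dn and 1669 without Dsn-2. Dsi against Mi (1645) gave 317 with DESeq2, 115 with a mean of at least 50 reads, 717 without batch, and 907 and 877 with the removals, and 178 (without Mi-2) to 2116 (without Dsn-1), with 809 without Dsi-1 and 1029 without Mn-1. Dsn against Mn (151) gave 9 with a mean of at least 50 reads and 0 without batch (2491 unadjusted), and 0 (without Mn-2, 1213 unadjusted) to 260 (without Di), with 77 without Dn, 253 without Dsi-1 and 237 without Dsi-2. DESeq2 called 130 there, of which 45 were shared. The 21 nt share difference (7.71 points) was -2.33 among reads not matching a virus contig, because virus reads are mostly 21 nt long, and 4.37 to 10.3 over left-out libraries. The 22 nt difference ranged from 0.511 to 1.44. The 24 nt difference (-4.86) was -0.408 among reads not matching a virus contig (exact p = 0.667), -5.71 over distinct sequences (exact p = 0.0381) and -5.99 to -3.16 over left-out libraries. The virus share difference (23.7) was 19.2 for contigs with a marker only (exact p = 0.0476), 35.5 without the Dsn libraries (exact p = 0.0286), and 16.6 to 28.4 over left-out libraries. In virus small RNA make-up per group, the mean sense share of CymMV reads (58.1%) was 54.3% over distinct sequences. Of the other values, for single families, sequences and a ratio, 1300 kept their direction and side of the threshold, 120 no longer passed, 17 passed in addition, and 52 that were not called changed sign or, in the ratio of 22 nt to 21 nt, size. Of the 120, 81 were of families and 39 of sequences. Many of the 1300 belong to families named whatever their p, which had no call to lose. The 1300 therefore do not measure how stable the calls were.

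With the replicate number as a replicate block among Mi, Mn, Dsi and Dsn, family counts were 2 in infected against mock, 2 in Dsi against Mi, 7 in Dsn against Mn, 0 in Dsi against Dsn (5 unadjusted) and 6 in Mi against Mn, all higher in Mi, and host sequence counts were 1101, 1559 and 328. Calls that ended included miR168 (1.41, adjusted p = 0.119) and miR319 (2.02, adjusted p = 0.0643) in Dsi against Mi and miR168 (1.64, adjusted p = 0.133) in Dsi against Dsn. Deviations by number correlated over families at 0.714 between Mi and Mn, where the number equals the batch, at 0.646 between Dsi and Dsn, and at -0.337 to 0.0871 otherwise. Over host sequences the values were 0.688, 0.196 and 0.00501 to 0.0776. The numbers were not taken to pair samples.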

Other observations

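The tests of pairing with the miR168 variant and of splits without virus-like sequences were chosen only after the result was seen. The variant TCGCTTGGTGCAGGTCGGGAC and the unnamed CCTGCCTTGCATCAACTGAAT were both highest where both viruses were abundant. The variant stood at 2553 RPM in Dsi and 2162 in Di, against 325 in Dn, 180 in Mn, 173 in Mi and 99.2 in Dsn. The other sequence stood at 511 in Dsi and 281 in Di, against 87.5 in Dn, 61.7 in Mi, 46.8 in Mn and 41.4 in Dsn. The pair matched at 17 of 19 positions, 4 of them G to U, with overhangs of 2 nt. Of 7374 tested sequences of 21 nt, 2 reached 17 pairs, where the median was 8. The other of them paired better, at 18 positions, and did not pass in Dsi against Mi, so pairing alone does not single out CCTGCCTTGCATCAACTGAAT.

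The copper-responsive families varied most among batch 1 libraries. There miR398 stood at 2.66 RPM in Mi-1, 21.5 in Mn-1, 28.7 in Di and 50.4 in Dn, and miR528 at 93.9, 433, 365 and 530. In batch 2 miR398 lay between 3.89 and 13.8 RPM and miR528 between 178 and 257. Mi-1 was thus the low library, and miR398 in Di against Mi fell from 2.33 to 0.74 without it.

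The 10 libraries were also split at random into 6 and 4 for infected against mock. For families the real split called 3. Of 100 splits, the real one included, 4 called as many, with 5 as the highest other. This lay just under the bound of 5 in 100 set in advance. The margin is too narrow to exclude chance firmly. Only 100 of the 209 splits that could be fitted were used, and not all kept the batch balance of the real one. For host sequences the real split called 981, alone among 60 splits (1 of 60) and under the same bound, and the highest other called 614. That split exchanged Mn-1 and Dn. The margin for host sequences rested partly on virus-like ones. Without them the real split called 614, and 2 of 60 splits, the real one included, called as many, still under the bound of 5 in 100. The split that called more, 1026, was Dsi and Dsn against the rest, which with batch in the fit compares Ds with mock inside batch 2, so the calls followed a structure of that batch. With virus-like sequences kept, 1603 passed with batch 2 only and 42 with batch 1 only. For family lists the real split called 0 by camera (0 unadjusted), and the highest other 0, so that 100 of 100 splits called as many by necessity, which says nothing about chance.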
